A study of Mus musculus with 9 samples.

How the data were processed

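RNA was measured in 9 libraries of mouse cardiomyocytes, the contractile muscle cells of the heart, in 3 groups of 3. Per the labels, total RNA was taken with TRIzol from isolated cardiomyocytes, ribosomal RNA was depleted, and directional libraries were sequenced as 150-bp paired-end reads on an Illumina NovaSeq instrument. The same labels give the molecule as polyA RNA, so whether transcripts without a polyA tail were kept is not settled. Per the submitters' processing notes, the tools were FastQC, Trimmomatic, STAR and featureCounts and the build was mm10; versions and parameters are not given in the sources used here. The deposited values are raw counts per Ensembl gene, not normalized, and the table closes with 5 lines of unassigned reads named in the way HTSeq names them, so the program that made the counts is also not settled.

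Those 5 lines named no gene and stayed out of library sizes and tests; they held 16.3% to 17.4% of all counts per library, of which 5.43% to 6.55% were in no annotated gene, 2.85% to 3.45% were ambiguous and 7.06% to 8.21% were not uniquely aligned. Of 55487 gene identifiers, 55227 matched the GENCODE M21 annotation on the mm10 (GRCm38) build, from which symbols, gene types and coordinates were taken; the 260 others held 0.0016% of the counts. The kit marks strand, but whether the counting used it is not stated, so values of overlapping and antisense genes are uncertain. Genes with near-identical copies, among them the replication-dependent histones and the H2, Gbp, Ifit and Oas families, are likewise uncertain because reads shared between copies may have been dropped or split.

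Groups were taken from the sample titles, and each count column was matched to its sample by the column name in the sample's description. The titles call the samples biological replicates without saying whether they are separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Replicates of a group were compared by a chi-square test of their counts over genes with at least 100 counts; the statistic per degree of freedom was 3.27 to 7.39, above sampling noise for each pair, and the 3 libraries of each group were kept as 3 replicates. The labels name no sequencing date, culture or vector batch, so any such batch and the group cannot be told apart.

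The design, the 46 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, robust prior) with TMM normalization, the filterByExpr low-count filter (minimum count 10, minimum total 15) and no covariates. All 9 libraries entered a single fit with 6 residual degrees of freedom, 15633 genes were tested, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Expression levels are CPM, counts scaled to library size with TMM factors, and given as mean ± SD. Fold changes are on the log2 scale with a standard error (SE). The SE was derived from the test, as the absolute log2 fold change over the square root of the F statistic. A gene with 0 counts in a group was given a bound against a floor of 3 counts over that group, and a gene with 1 to 3 counts a ratio with an exact 95% counting interval. A bound allows for counting error in the group with 0 counts and takes the counts of the other group as exact. Bounds and intervals cover no error other than that of counting, since the reads carry no molecular identifiers.

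Gene lists with at least 5 tested members, 43 of the 46, were tested with camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01, adjusted over the lists. Of 972 genes written by symbol, 971 were in the table. The test was repeated with an estimated correlation and with fry, whose directional p asks whether a list's genes move one way on balance and not whether they differ from other genes. Counts of members that rose or fell use the adjustment over all genes tested unless they are said to be adjusted over the list alone. Fold changes of lists and genes were checked under each scaling.

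The genes named are Firre, Ptbp1, Akt1 and Akt2 in every comparison. To these were added the genes with the largest fold change among those past the threshold with a mean of at least 2 CPM in the higher group, non-overlapping groups and an established symbol (8 per direction for Firre overexpression against the negative control, 5 for the other comparisons), filled up to 5 with the smallest p where fewer passed. From each of the up to 8 lists with the smallest camera p, and from 5 lists named in advance, the 3 members with the smallest p were taken. Some genes that the rule covers are not reported here.

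The scripts were tested on simulated counts for Firre overexpression against the negative control, drawn for 15389 genes. edgeR recovered 62.0% of 50 genes changed by 0.5 on the log2 scale, 82.7% of 75 changed by 1 and 97.3% of 75 changed by 2. In the same run 19 calls were wrong, 9.74% of all calls, and 1 gene was called in the simulated comparison with no change. That share of wrong calls lay above the threshold of 0.05. A further small set of genes, shifted by less, was not counted as wrong. Few of the simulated genes were changed, whereas edgeR called 56.0% in the real comparison, so these rates need not hold there.

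Alternatives were DESeq2 size factors, upper-quartile scaling and library totals in place of TMM; no filter and a stricter filter of 1 CPM in 3 samples; DESeq2 1.42.0 and limma-voom; fits of 2 groups alone; the replicate number as a block; no robust prior; a log2 threshold of 1; protein-coding genes alone; and leaving out each library in turn. Overlap of comparisons that share libraries was set beside 20 simulations of unchanged groups. Figures were drawn with matplotlib 3.10.9. Splicing, the RNA-binding experiments that the series title implies, protein phosphorylation and the sequence of the vector were not analysed here.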

Results

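To ask how raised levels of the long noncoding RNA Firre alter gene expression in heart muscle cells, RNA was sequenced from isolated mouse cardiomyocytes in 3 groups of 3 libraries. One group carried an AAV9 vector for Firre overexpression, an adeno-associated virus serotype that infects heart muscle well. The negative control carried the AAV9 control vector, and the blank control is labelled only as a blank. Counts assigned to genes totalled 15591542, 20193373 and 17362352 in the blank control libraries, 19252992, 20868139 and 19404965 in the negative control libraries and 20273298, 22697016 and 19639687 in the Firre libraries, and each library had counts in 21222 to 21878 genes. Mitochondrially encoded genes took 6.50% ± 0.288 of the counts in the blank control, 6.19% ± 0.382 in the negative control and 7.65% ± 0.514 in the Firre group (SD, n = 3 each), and the 10 most abundant genes of a library took 9.88% ± 0.268, 9.58% ± 0.262 and 12.1% ± 0.380. The deposited values are counts, and the biological coefficient of variation in the fit was 5.96%.

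Firre itself, an X-linked RNA that stays in the nucleus and binds chromatin and nuclear matrix proteins, was higher in each Firre library than in any of the 6 controls. Its level was 62.9, 69.7 and 62.6 CPM in the Firre libraries, against 32.5, 34.4 and 32.7 CPM in the negative control and 34.0, 37.2 and 30.2 CPM in the blank control. The group means were 65.0 ± 4.02, 33.2 ± 1.05 and 33.8 ± 3.47 CPM (SD, n = 3). Firre (ENSMUSG00000085396) is annotated as a processed transcript on the minus strand of chromosome X, from 50555744 to 50635321 in mm10. The difference between the Firre and negative control groups was a log2 fold change of 0.97 (SE 0.07, edgeR adjusted p = 4.74e-13), and the negative control did not differ detectably from the blank control (-0.03, SE 0.07, adjusted p = 0.954). A single count per gene holds reads of the chromosomal gene and any vector reads that aligned to it, so their shares are not known.

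The series title names myocardial proliferation, PTBP1, a splicing repressor that binds pyrimidine tracts, and the kinase Akt, which passes growth factor signals to metabolism and survival. Ptbp1 mRNA fell by 0.81 on the log2 scale (SE 0.05, adjusted p = 2.55e-14), from 298 ± 14.7 CPM in the negative control to 170 ± 8.33 CPM with Firre (SD, n = 3). Akt2, the isoform best known for insulin-driven glucose uptake, rose by 0.33 (SE 0.05, adjusted p = 6.65e-07), from 153 ± 3.40 to 193 ± 9.18 CPM. Akt1 had a value of -0.07 (SE 0.05, adjusted p = 0.212) and did not pass the test. With library totals alone as the scaling, Akt1 passed at -0.13 (adjusted p = 0.0253, with a range over all alternatives of 0.0253 to 0.610). These are mRNA levels and do not measure the phosphorylation that activates Akt.

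**Figure D1:**
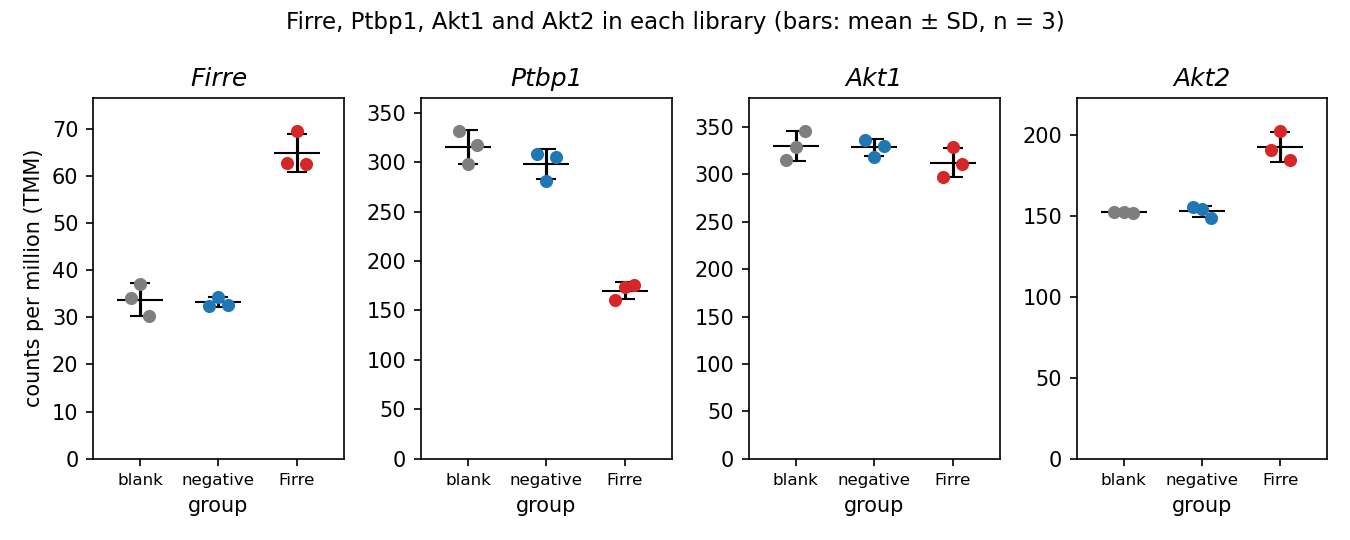
Levels of Firre, Ptbp1, Akt1 and Akt2 in CPM (y axis) in each library of the 3 groups (x axis); points are libraries and bars are mean ± SD, n = 3. The 3 Firre libraries lie at 62.6 to 69.7 CPM for Firre and at 161 to 176 CPM for Ptbp1, above and below all 6 controls respectively.

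Between the Firre and negative control groups, among genes with at least 2 CPM in the higher group, groups that did not overlap and an established symbol, the 8 with the largest rise included 3 of the interferon-stimulated list (Rsad2, Oasl1 and Ifit1) and 2 of the inflammatory list (Ccl5 and Cxcl10), and the 8 with the largest fall included 3 macrophage markers (Lyz2, Adgre1 and C1qa). Ccl5, a chemokine that draws T cells and monocytes, rose by 6.73 on the log2 scale (SE 0.16), from 0.400 ± 0.0670 to 43.0 ± 3.17 CPM, and the interferon-induced chemokine Cxcl10 rose by 5.63 (SE 0.25), to 90.0 ± 10.8 CPM (SD, n = 3). Rsad2, which encodes the antiviral enzyme viperin, rose by 5.47, the interferon-induced guanylate-binding protein genes Gbp10 and Gbp4 by 5.39 and 4.43, Oasl1 by 4.55 and Ifit1 by 4.47; Gsta2, a glutathione transferase of the NRF2 list, rose by 4.63. Cxcl10 and Gbp4 were low and uneven in the negative control (1.82 ± 1.14 and 0.318 ± 0.218 CPM), and without negative control replicate 1 their values were 6.25 and 5.10. In the other direction, the lysozyme gene Lyz2 fell by 5.30 (SE 0.16), from 29.8 ± 2.37 to 0.738 ± 0.303 CPM. Adgre1, which encodes the macrophage surface marker F4/80, fell by 5.41, and the chemokine gene Ccl6 fell by 6.48.

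The complement gene C1qa had 0 counts in all 3 Firre libraries, at least 44.2-fold lower than in the negative control, and Wfdc17 also had 0, at least 43.2-fold lower. Spi1, the master transcription factor of myeloid cells, had 3 counts over the Firre group, a ratio of 49.3 with a 95% counting interval of 16.5 to 242. Clec4n, a lectin receptor, had 2 counts (ratio 117, 32.1 to 975) and the antibody receptor gene Fcgr2b had 3 (ratio 48.6, 16.3 to 238). All 16 of these genes passed, the adjusted p being highest for Ifit1 at 5.94e-06. Reads of the Gbp and Ifit families can be shared between copies, so their folds are uncertain.

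In all, edgeR called 8747 of 15633 genes (56.0%), 4306 higher and 4441 lower with Firre, and 9379 genes had an unadjusted p under 0.05. Of the called genes 1878 changed at least 2-fold, 764 higher and 1114 lower. The groups did not overlap in 62.4% of the genes tested, where chance gives 10% for 3 against 3. Log2 levels correlated across genes at 0.991 to 0.992 within the Firre group and at 0.957 to 0.961 between Firre and negative control libraries; genes are not independent replicates. With library totals alone as the scaling, 3685 genes were called higher and 5050 lower, and the median of all genes was -0.05. A vector preparation or a culture batch, if the groups differed in one, is not named in the labels and could not be separated from the group.

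**Figure D2:**
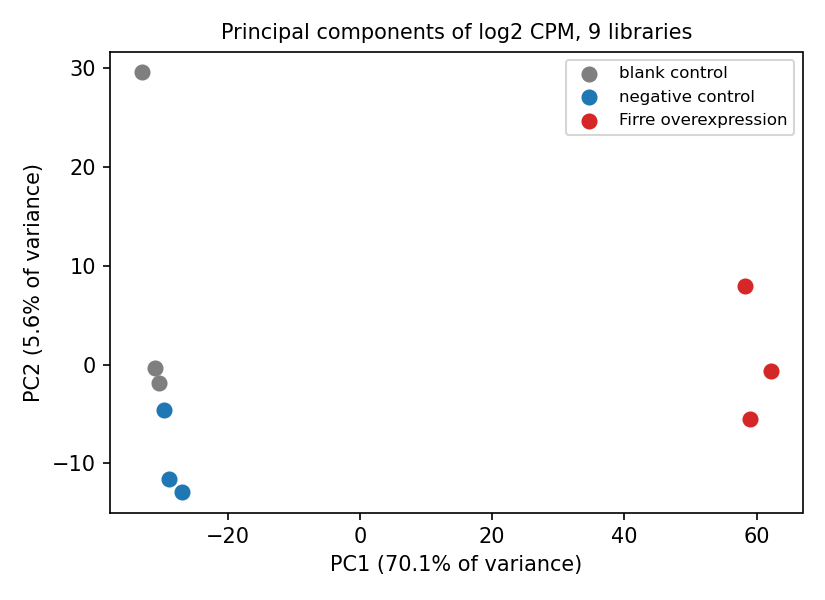
The first and second principal components of log2 CPM (x and y axes, with their share of the variance) for the 9 libraries; each point is a library, coloured by group. The first component, 70.1% of the variance, parts the 3 Firre libraries from the 6 controls, and the second holds 5.59%. On the second, blank control replicate 1 lies at 29.5 and the other libraries between -12.8 and 7.91.

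All 44 interferon-stimulated genes tested rose with Firre, with a median log2 fold change of 2.66 and a range of 0.39 to 5.47. Besides Rsad2 and Oasl1, the transcription factor gene Irf7, which drives interferon production, rose by 2.36 (SE 0.05, adjusted p = 8.32e-26), from 121 ± 2.14 to 621 ± 17.1 CPM (SD, n = 3). Camera called the list (adjusted p = 7.73e-34), also with an estimated correlation (adjusted p = 0.0315). The inflammatory cytokine and NF-kB target list went the other way, with 18 of 32 members lower and 4 higher at a median of -0.37 (camera adjusted p = 4.61e-03, and adjusted p = 0.395 with an estimated correlation). Ccl5 and Cxcl10 belong to that list, and Ccl5 had its highest value. Over the same comparison 15 of 17 macrophage markers fell and none rose, at a median of -3.87 that was the same with C1qa at its bound.

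Genes of the contractile apparatus rose together. All 29 sarcomere genes tested rose, at a median of 0.78, among them the Z-disc gene Ldb3 by 1.27 (SE 0.05), the atrial myosin light chain gene Myl7 by 1.73 (SE 0.05) and the thin-filament capping gene Tmod1 by 1.09 (SE 0.05). Of 34 genes of calcium handling and ion channels, 31 rose and 2 fell (median 0.62). Atp2a2, the calcium pump of the sarcoplasmic reticulum, went from 3294 ± 56.2 to 7034 ± 154 CPM (log2 1.09, SD, n = 3), the acetylcholine-gated potassium channel gene Kcnj3 rose by 1.42, and Sln, whose product restrains the calcium pump, by 1.26. Camera called both lists (adjusted p = 1.34e-19 and 8.49e-14), also with an estimated correlation (adjusted p = 0.0315 for each). In the same libraries 17 of 18 fibroblast markers fell (median -1.12).

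Atrial markers rose by more than ventricular markers. Of 13 atrial markers 12 rose and 1 fell, with a median of 1.26, and of 10 ventricular markers 8 rose and 1 fell, with a median of 0.38. The difference of the medians, a contrast chosen after they were seen, was 0.88, with a 95% bootstrap interval of 0.61 to 1.20. It was 0.87 to 1.05 when each Firre library was taken alone. The bootstrap drew genes of the lists, not libraries, and genes are not independent replicates. Myl4 and Nppa, the genes of the fetal myosin light chain and of atrial natriuretic peptide, rose by 1.53 (SE 0.05) and 0.95 (SE 0.05). They belong to the fetal and hypertrophy list, in which 14 of 24 members rose and 8 fell (median 0.36, camera adjusted p = 0.0368, and adjusted p = 0.271 with an estimated correlation). Developmental cardiac transcription factors went both ways too, with 18 of 27 higher and 7 lower (median 0.32, adjusted p = 4.73e-03, and adjusted p = 0.0843 with an estimated correlation). Camera called the atrial and ventricular lists with adjusted p values of 5.05e-11 and 3.24e-03, and of 0.0160 and 0.0416 with an estimated correlation. Endothelial markers fell in these libraries, 17 of 20 at a median of -1.05.

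Fuel metabolism genes of the mitochondria were higher with Firre. Of 34 fatty acid oxidation genes 33 rose and none fell, at a median of 0.98; Acaa2, the last thiolase step, rose by 1.28 (SE 0.05), the dehydrogenase gene Acadl by 1.08 (SE 0.05) and Acsl1, which activates long-chain fatty acids, by 1.06 (SE 0.05). Camera called the list (adjusted p = 1.34e-19), also with an estimated correlation (adjusted p = 0.0315). Of 85 nuclear-encoded subunits of oxidative phosphorylation 81 rose and 2 fell (median 0.57), with the ATP synthase genes Atp5g1 and Atp5c1 at 0.91 and 0.73 and the complex III gene Uqcrc2 at 0.79. That call had an adjusted p of 7.65e-25, and of 0.0513 with an estimated correlation. Among 15 mitochondrially encoded genes 7 rose and 1 fell (median 0.33, adjusted p = 0.0105, and adjusted p = 0.416 with an estimated correlation), and among 21 glycolysis genes 11 rose and 5 fell (median 0.19, adjusted p = 0.0371, and adjusted p = 0.345 with an estimated correlation). Fibroblast and macrophage markers fell in the same libraries, at the medians of -1.12 and -3.87 given for the other groups.

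Proliferation, which the series title has Firre promote, was followed here by transcripts alone, and assays of dividing cells are not analysed here. Proliferation genes were lower with Firre. All 40 genes of mitosis and G2/M fell, at a median of -0.89: Mki67, the gene of the Ki-67 antigen, fell by 1.15 (SE 0.06), from 148 ± 7.41 to 66.6 ± 4.22 CPM (SD, n = 3), the anaphase activator gene Cdc20 by 1.21 (SE 0.08) and the topoisomerase gene Top2a by 0.91 (SE 0.05). Of 40 genes of DNA replication and G1/S 37 fell and none rose (median -0.72), with the nucleotide synthesis genes Rrm1 and Tyms at -0.69 and -1.02 and Uhrf1, which maintains DNA methylation after replication, at -0.89. Camera called both lists (adjusted p = 1.89e-17 and 2.65e-11), also with an estimated correlation (adjusted p = 0.0416 and 0.0404). Of 18 cell cycle inhibitors 6 rose and 7 fell, and the list was not called (adjusted p = 0.999); its median was 0.05, its mean -0.16, and with library totals alone its median was -0.01. The bulk counts do not say in which cell type these genes were expressed, and 17 of 18 fibroblast markers fell with them (median -1.12).

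Replication-dependent histone genes, most of whose transcripts normally lack a polyA tail, went against the other S-phase genes: 18 of 20 rose and none fell (19 rose when adjusted over the list alone), at a median of 1.33 and a range of 0.40 to 3.06 (camera adjusted p = 2.87e-06, and adjusted p = 0.0315 with an estimated correlation). These genes share reads between copies and are uncertain. Only 11 of the 20 reached 1 CPM in the negative control. Genes low in the controls could enter the test through their counts in the Firre libraries alone, so the share that rose may be inflated. Of 17 small nucleolar RNAs and their host genes 4 rose and 3 fell (adjusted p = 0.947; 2 rose and 2 fell adjusted over the list alone), and of 9 long nuclear RNAs 4 fell and none rose (median -0.31, adjusted p = 0.0761). Ribosomal protein genes were not called, with 5 of 79 higher and 23 lower at a median of -0.07 (adjusted p = 0.0761; 5 and 21 adjusted over the list alone). Macrophage and fibroblast markers fell in the same libraries, 15 of 17 and 17 of 18.

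Markers of several other cell types of the heart were lower with Firre, by amounts that differed between them. Macrophage markers had a median of -3.87 and epicardial and mesothelial markers one of -1.86, with 15 of 17 and 12 of 12 lower. Fibroblast markers (17 of 18 lower, 18 adjusted over the list alone, median -1.12), smooth muscle and pericyte markers (11 of 13 lower, 2 higher, median -1.07) and endothelial markers (17 of 20 lower, 1 higher, median -1.05) lay closer together. Among the endothelial genes Vwf, the clotting glycoprotein, fell by 3.38 (SE 0.09), from 66.0 ± 2.59 to 6.31 ± 1.44 CPM, the junction gene Cdh5 by 1.42 (SE 0.05) and the receptor gene Tie1 by 1.76 (SE 0.06; SD, n = 3). Camera called these 5 lists with adjusted p values of 4.09e-07, 2.64e-09, 3.28e-11, 1.65e-04 and 2.65e-11. With an estimated correlation the adjusted p was 0.0350, 0.0315, 0.0315, 0.0541 and 0.0229, so the smooth muscle call was lost. Schwann cell and neuron markers (2 of 8 higher, 3 lower, adjusted p = 0.691) and adipocyte markers (2 of 6 higher, 2 lower, adjusted p = 0.780) were not called. The 1 neutrophil marker and 2 of 3 lymphocyte markers tested were lower, too few for a list test.

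Matrix genes fell with those markers. Of 39 genes of extracellular matrix and fibrosis 38 fell and none rose (median -0.96): the fibronectin gene Fn1 went from 6849 ± 124 to 2347 ± 118 CPM (log2 -1.54, SE 0.05; SD, n = 3), the fibulin gene Fbln2 fell by 1.62 (SE 0.05) and Tgfbi, which TGF-beta induces, fell by 2.09 (SE 0.06). The call held with an estimated correlation (adjusted p = 4.10e-26 and 0.0315). Angiogenic factors and receptors fell in 18 of 27 and rose in 6 (median -0.47, adjusted p = 3.54e-04, and adjusted p = 0.0315 with an estimated correlation). YAP target genes fell in 17 of 23 and rose in 2 (18 and 2 adjusted over the list alone; median -0.35, adjusted p = 3.76e-05, and adjusted p = 0.0611 with an estimated correlation). Immediate early genes fell in 14 of 27 and rose in 2 (14 and 3 adjusted over the list alone; median -0.28, adjusted p = 7.71e-03, and adjusted p = 0.176 with an estimated correlation). Fibroblast markers fell alongside these lists, at the median of -1.12.

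For the Akt pathway, 19 of 40 components rose and 10 fell (20 and 10 adjusted over the list alone). The median was 0.08 and the mean -0.09, and camera did not call the list (adjusted p = 0.643). The 3 members with the smallest p all fell: the stem cell factor receptor gene Kit by 2.30 (SE 0.10), the neuregulin gene Nrg1, whose product is a growth factor for cardiomyocytes, by 2.08 (SE 0.07), and the growth factor receptor gene Egfr, which fell by 1.79 (SE 0.07). FOXO targets, which Akt signalling normally holds down, rose in 17 of 26 and fell in 4 (median 0.29, adjusted p = 5.08e-04, and adjusted p = 0.0315 with an estimated correlation). Other fixed lists also hold 11 of the 26, so the rise is not specific to Akt signalling and does not measure it. Endothelial and fibroblast markers fell in the same libraries, 17 of 20 and 17 of 18.

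Of the PTB family and other heterogeneous nuclear ribonucleoproteins, 15 of 27 fell and 1 rose (median -0.18, camera adjusted p = 2.08e-03, and adjusted p = 0.0513 with an estimated correlation). Of 18 genes neighbouring Firre on chromosome X 6 rose and 5 fell (7 and 5 adjusted over the list alone; adjusted p = 0.691), and of 5 genes at loci bound by Firre in other cells 2 rose and 3 fell (adjusted p = 0.966). Stress lists gave mixed results. Heat shock protein genes rose in 15 of 21 and fell in 1 (median 0.31, adjusted p = 3.95e-05, and adjusted p = 0.0404 with an estimated correlation), and NRF2 antioxidant genes, Gsta2 among them, rose in 14 of 28 and fell in 4 (median 0.26, adjusted p = 7.71e-03, and adjusted p = 0.293 with an estimated correlation). Cholesterol synthesis genes fell in 13 of 23 and rose in 1 (median -0.20, adjusted p = 0.0195, and adjusted p = 0.597 with an estimated correlation); without negative control replicate 2 that call was lost (adjusted p = 0.151, where all alternatives spanned 3.48e-03 to 0.597). Macrophage and fibroblast markers fell in the same libraries, at medians of -3.87 and -1.12.

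Not called were apoptosis regulators (2 of 28 higher, 15 lower, adjusted p = 0.0598; 4 and 15 adjusted over the list alone), the unfolded protein response (13 of 38 higher, 15 lower, adjusted p = 0.691; 13 and 16 adjusted over the list alone), hypoxia genes (5 of 22 higher, 10 lower, adjusted p = 0.284) and p53 targets. Of 25 p53 targets 8 rose and 9 fell, and the median was 0.05 but -0.01 with library totals alone (adjusted p = 0.456). Sex-linked genes were not called either (1 of 5 higher, adjusted p = 0.691), with a median of 0.05 that was -0.01 with library totals alone. Among lists that were not called, the median and the mean differed in sign for the unfolded protein response (-0.02 and 0.09) and for loci bound by Firre in other cells (-0.16 and 0.09), and camera's direction was up against a negative median for adipocyte markers (-0.15) and small nucleolar RNAs (-0.07). Where no other number is given, counts adjusted over the list alone were those given over all genes tested, apart from cell cycle inhibitors, where 7 rose. Of the 43 lists tested camera called 29, 15 up and 14 down; 17 of these were called with an estimated correlation and fry called 36. Leaving out 1 library brought in the apoptosis list without negative control replicate 1 (adjusted p = 0.0468), without Firre overexpression replicate 1 (0.0477) or without Firre overexpression replicate 3 (0.0489). The ribosomal list came in, as lower, without negative control replicate 2 (7.57e-03) or Firre overexpression replicate 3 (0.0148), and the long nuclear RNAs without Firre overexpression replicate 1 (0.0424). Over all alternatives the adjusted p was 1.29e-04 to 0.115 for apoptosis regulators, 7.57e-03 to 0.795 for ribosomal protein genes and 7.10e-05 to 0.201 for long nuclear RNAs.

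**Figure D3:**
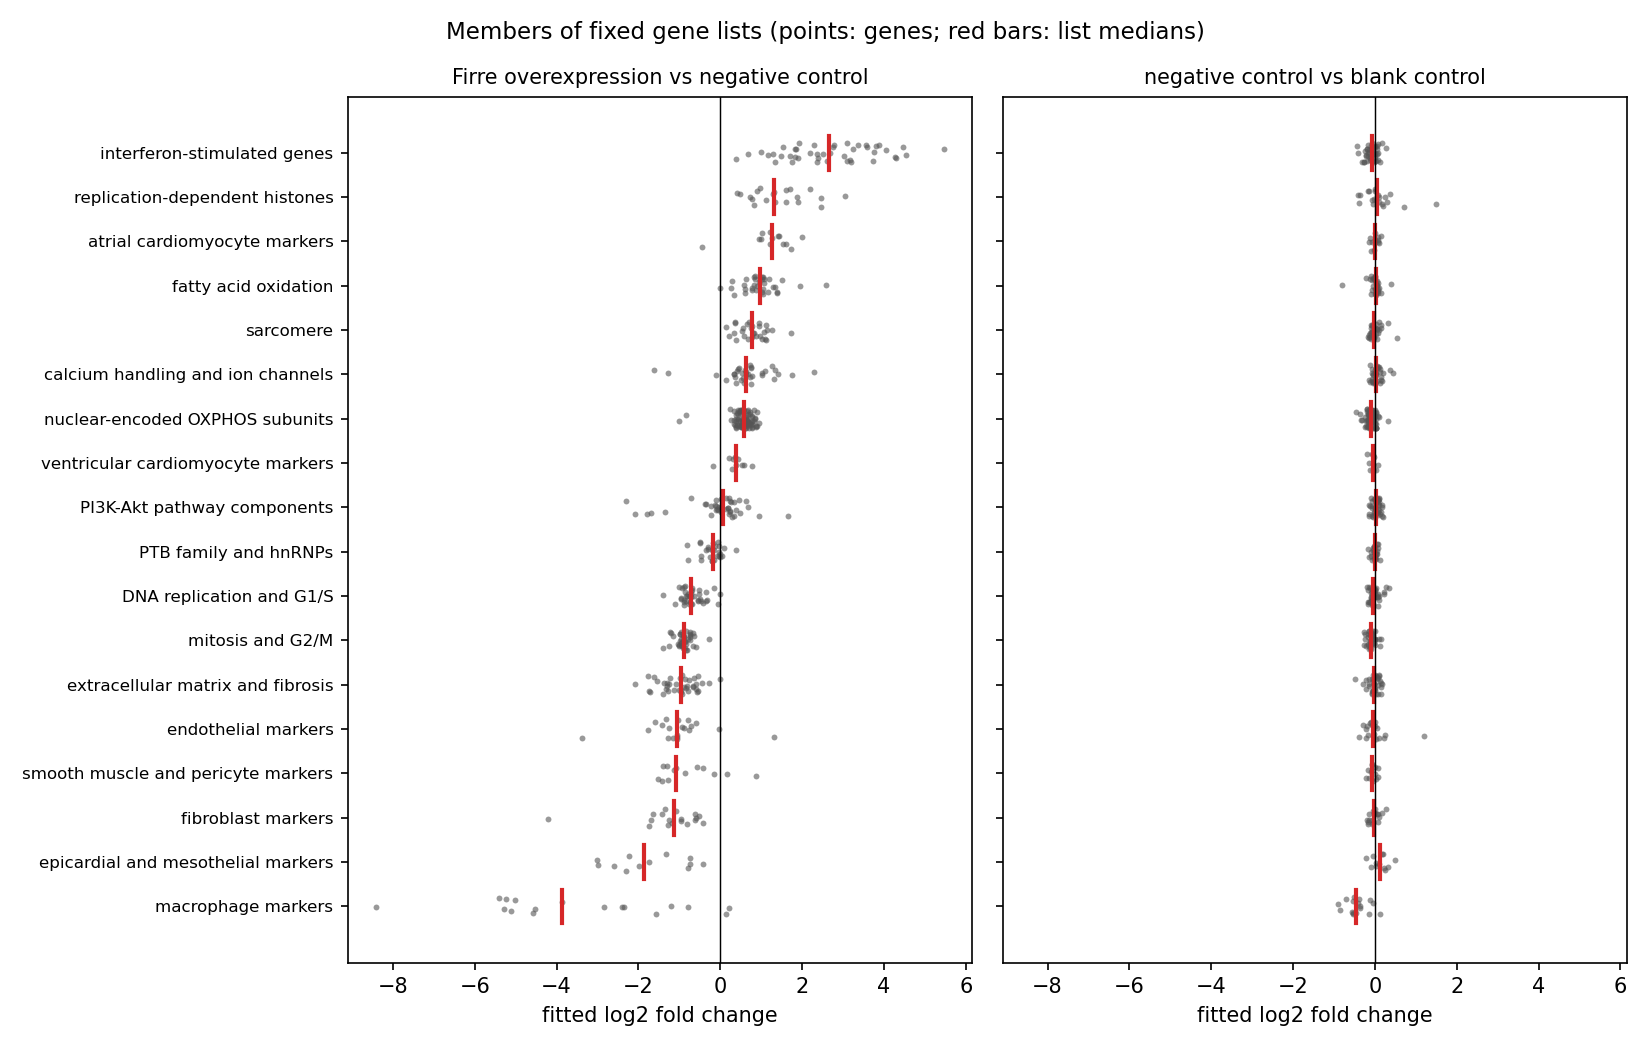
Fitted log2 fold change (x axis) of the tested members of 18 fixed gene lists (y axis), for Firre overexpression vs negative control and for negative control vs blank control; each point is a gene and each red bar a list median. With Firre the medians run from -3.87 for macrophage markers to 2.66 for interferon-stimulated genes; between the controls those of these lists lie between -0.45 and 0.13.

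The negative control was next set against the blank control, whose label does not say whether it received any vector. Few genes differed. Cmya5, a muscle gene whose protein lies at the Z-disc and costamere, rose by 0.24 (SE 0.05, adjusted p = 0.0423), from 210 ± 8.54 to 248 ± 8.16 CPM (SD, n = 3). Ccl6 fell by 0.76 (SE 0.11, adjusted p = 5.05e-03), the interleukin-1 receptor antagonist gene Il1rn by 0.55 (SE 0.11, adjusted p = 0.0423), the metalloprotease gene Adam8 by 0.55 (SE 0.10, adjusted p = 0.0147), the fetuin-A gene Ahsg by 0.42 (SE 0.09, adjusted p = 0.0476) and Vwf by 0.39 (SE 0.07, adjusted p = 0.0360). Also lower were Irf7 by 0.31 (adjusted p = 4.19e-03), the antiviral membrane protein gene Ifitm3 by 0.28 (adjusted p = 0.0423) and the predicted gene Gm4617 by 0.64 (adjusted p = 0.0147), which are named here after their values were seen. Fasn (0.23), Svep1 (0.32), Thy1 (0.28) and Tnxb (0.33) had the next smallest p among higher genes and did not pass (adjusted p 0.114 to 0.136). Each of the 6 calls by the naming rule was lost under some alternative, which include other tools and settings as well as left-out libraries. Over all alternatives the highest adjusted p was 0.219 for Cmya5, 0.0712 for Ccl6, 0.357 for Il1rn, 0.143 for Adam8, 0.423 for Ahsg and 0.159 for Vwf. Ptbp1 (-0.08, adjusted p = 0.697), Akt1 (-0.01, 0.986) and Akt2 (0.01, 0.988) did not pass.

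In this comparison edgeR called 9 genes, 1 higher and 8 lower, and with upper-quartile scaling 0 higher and 8 lower. An unadjusted p under 0.05 was reached by 1331 genes (8.51%), and the groups did not overlap in 13.1% of genes, where chance gives 10%. The count rests on single libraries: it was 0 without blank control replicate 1, 55 without blank control replicate 2, 3 without negative control replicate 1, 4 without negative control replicate 2 and 15 without negative control replicate 3. Without blank control replicate 1, where edgeR called 0, 1037 genes had an unadjusted p under 0.05, and DESeq2 called 6 and limma-voom 0. That library had the fewest gene counts, 15591542, and lay apart from the others on the second principal component, at 29.5.

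Among gene lists, macrophage markers were lower in the negative than in the blank control at a median of -0.45. None of the 17 members passed over all genes tested, 9 fell when adjusted over the list alone, and the list was called by camera (adjusted p = 8.69e-11) and by fry (adjusted p = 0.0239) but not with an estimated correlation (adjusted p = 0.0879). Lyz2, Ctss and Pf4, genes of macrophages and platelets, had values of -0.40, -0.51 and -0.36 (adjusted p = 0.117, 0.114 and 0.141). Interferon-stimulated genes had a median of -0.08, with 1 of 44 lower, also when adjusted over the list alone (camera adjusted p = 0.0269, and adjusted p = 0.703 with an estimated correlation). Cholesterol synthesis genes had a median of 0.16, with 9 of 23 higher when adjusted over the list alone; Cyp51, Stard4 and Msmo1 were at 0.33, 0.25 and 0.24 (adjusted p = 0.346 with an estimated correlation for the list). Epicardial and mesothelial markers had a median of 0.13, with Msln, Lrrn4 and Upk1b at 0.32, 0.20 and 0.22 and 4 of 12 higher when adjusted over the list alone (adjusted p = 0.313 with an estimated correlation).

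Mitosis genes had a median of -0.09, with Cdk1, Birc5 and Tpx2 at -0.27, -0.26 and -0.21 and 1 of 40 lower adjusted over the list alone (adjusted p = 0.393 with an estimated correlation). Ribosomal protein genes had a median of -0.12, with 13 of 79 lower adjusted over the list alone and Rpl35, Rpl18 and Rpl35a at -0.25, -0.20 and -0.55 (adjusted p = 0.313 with an estimated correlation). Oxidative phosphorylation subunits had a median of -0.10, with Ndufs4, Ndufb11 and Cox7b at -0.22, -0.19 and -0.16 and none that passed adjusted over the list alone (adjusted p = 0.373 with an estimated correlation). For the unfolded protein response (median -0.08; Atf4, Ddit3 and Trib3 at -0.21, -0.20 and -0.17) and for small nucleolar RNA hosts (median -0.21; Gas5, Snhg1 and Snhg15 at -0.32, -0.37 and -0.31) the adjusted p was 0.313 with an estimated correlation, with 1 of 38 and 2 of 17 lower when adjusted over the list alone. None of these named members passed over all genes tested.

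The other lists camera called here were the fetal program (median -0.06, adjusted p = 0.373 with an estimated correlation), inflammatory genes (-0.06, 0.566), endothelial markers (-0.05, 0.313), mitochondrially encoded genes (-0.09, 0.657) and long nuclear RNAs (0.12, 0.313). Adjusted over the list alone, 5 of 20 endothelial and 1 of 32 inflammatory genes were lower, and none of the other 3 lists. In all camera called 14 of 43 lists, 3 up and 11 down; with an estimated correlation it called 0, with 5 lists at an unadjusted p under 0.05, and fry called 1. Camera's count was 9 without blank control replicate 1.

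Single libraries decided several of the list calls for negative control vs blank control. Without blank control replicate 1 the adjusted p was 0.682 for interferon-stimulated genes, 0.0639 for inflammatory genes, 0.191 for endothelial markers, 0.671 for mitochondrially encoded genes and 0.152 for long nuclear RNAs. The endothelial call was also lost without blank control replicate 2 (0.0684) or negative control replicate 1 (0.0779), and the inflammatory call without blank control replicate 3 (0.185) or negative control replicate 2 (0.0679). The fetal program was lost without blank control replicate 3 (0.0938), negative control replicate 1 (0.0779) or negative control replicate 2 (0.120). Interferon-stimulated genes were lost without negative control replicate 3 (0.858), mitochondrially encoded genes without negative control replicate 1 (0.408) or 3 (0.0704), and long nuclear RNAs without blank control replicate 3 (0.516) or negative control replicate 1 (0.137), 2 (0.127) or 3 (0.0538). Gained as higher were PI3K-Akt components without blank control replicate 2 (0.0173) or negative control replicate 3 (0.0464), sex-linked genes without blank control replicate 2 (0.0191), fatty acid oxidation without negative control replicate 2 (0.0306) and calcium handling without negative control replicate 3 (0.0272). Over all alternatives the lost calls spanned 2.39e-04 to 0.858 for interferon, 1.11e-04 to 0.566 for inflammatory, 4.25e-03 to 0.313 for endothelial, 5.73e-04 to 0.373 for fetal, 6.86e-04 to 0.707 for mitochondrially encoded and 0.0143 to 0.516 for long nuclear genes, and the gained ones 0.0173 to 0.516, 0.0191 to 0.832, 0.0306 to 0.975 and 0.0272 to 0.543 in the order given.

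Set against the blank control, Firre overexpression gave the interferon and macrophage changes again. Ccl5 rose by 6.69 (SE 0.16), Cxcl10 by 6.45 (SE 0.28), Rsad2 by 5.48, Gbp10 by 5.24 and Oasl1 by 4.39. C1qa, with 0 counts in the Firre group, was at least 83.4-fold lower and Wfdc17 at least 56.1-fold lower; Clec4n, with 2 counts, had a ratio of 126 (34.5 to 1049) and Cd300lf, a myeloid inhibitory receptor gene with 1 count, one of 170 (30.0 to 6739). Ccl6 fell by 7.24 (SE 0.23). Firre rose by 0.94 (SE 0.07, adjusted p = 1.07e-12), Ptbp1 fell by 0.89 (SE 0.05, adjusted p = 2.79e-15) and Akt2 rose by 0.34 (SE 0.05, adjusted p = 5.36e-07), while Akt1 (-0.08, adjusted p = 0.169) did not pass. With library totals alone Akt1 passed at -0.13 (adjusted p = 0.0235, with a range over all alternatives of 0.0235 to 0.602).

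Interferon-stimulated genes rose in 44 of 44 (median 2.55, with Irf7 at 2.05), sarcomere genes in 28 of 29 (median 0.82, with Ldb3 and Myl7 at 1.35 and 1.66), calcium handling and ion channel genes in 31 of 34 (median 0.67, with Atp2a2, Kcnj3 and Sln at 1.24, 1.57 and 1.34) and fatty acid oxidation genes in 32 of 34 (median 0.91, with Acaa2, Acadl and Acsl1 at 1.32, 1.08 and 1.12). Oxidative phosphorylation subunits rose in 75 of 85 and fell in 2 (median 0.50, with Uqcrc2, Sdha and Atp5b at 0.80, 0.71 and 0.67; 76 and 2 adjusted over the list alone), and this call was lost with an estimated correlation (adjusted p = 0.0678). Mitosis genes fell in 40 of 40 (median -0.96, with Mki67, Top2a and Tpx2 at -1.20, -0.99 and -1.14), DNA replication genes in 38 of 40 (median -0.76, with Tyms, Mcm6 and Rrm1 at -1.08, -0.89 and -0.70) and matrix genes in 38 of 39 (median -0.98, with Tgfbi, Fbln2 and Fn1 at -2.30, -1.63 and -1.47). Macrophage markers fell in 15 of 17 and rose in 1 (median -4.41), and fibroblast markers fell in 18 of 18 (median -1.22).

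Ribosomal protein genes, which camera did not call against the negative control, fell in 47 of 79 and rose in 4 here (48 and 4 adjusted over the list alone, where the other lists named had the counts given; median -0.22, adjusted p = 2.29e-05, and adjusted p = 0.424 with an estimated correlation). Cholesterol synthesis genes, called lower against the negative control, were not called here (4 of 23 higher, 6 lower; 2 and 5 adjusted over the list alone; adjusted p = 0.546, all alternatives 0.380 to 0.915). Their median was 0.03, but -0.02 with library totals alone, and their mean was -0.09. The fetal program (median 0.34, adjusted p = 0.0642) and mitochondrially encoded genes (median 0.16, adjusted p = 0.0567) were not called here either. edgeR called 8796 genes, 4273 higher and 4523 lower, of which 1954 changed at least 2-fold. Camera called 27 of 43 lists, 13 up and 14 down, of which 16 were called with an estimated correlation, and fry called 36. For Firre overexpression vs blank control, leaving out 1 library brought in apoptosis regulators, as lower, without Firre overexpression replicate 1 (adjusted p = 0.0438) or 3 (0.0469), and mitochondrially encoded genes, as higher, without Firre overexpression replicate 2 (7.05e-03) or blank control replicate 1 (6.97e-03), where all alternatives spanned 8.68e-05 to 0.101 and 6.97e-03 to 0.555.

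Of the genes called against either control, 7697 were called against both in the same direction, 3741 higher and 3956 lower, and 0 in opposite directions. Simulated unchanged groups that share the Firre libraries gave 0.05 on average over 20 simulations, and independent lists of the same sizes would share 2462. With no change simulated, few genes are called at all. The 0.05 is therefore low by construction and does not measure what the shared libraries add to the 7697. Log2 fold changes of the 2 comparisons had r = 0.96 across genes against 0.49 in the simulations, and a covariance of 0.615 against 0.0202. The comparisons share the 3 Firre libraries, too few to split into sets of at least 2, so part of the excess over independent lists may come from those shared libraries.

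Of the 9 genes called between the controls, 2 moved the opposite way with Firre and 7 moved the same way. Irf7 and Ifitm3 were lower in the negative than in the blank control and rose with Firre, by 2.36 (SE 0.05) and 1.07 (SE 0.06). Ccl6, Il1rn, Adam8, Ahsg, Vwf and Gm4617 fell in both comparisons and Cmya5 rose in both. Simulated unchanged groups gave 0.10 opposed genes on average, with a highest count of 2 that equals the observed one, and 0 that moved the same way, and independent lists would give 2.49 and 2.55. Few genes are called in such simulations, so their counts are low by construction. The log2 fold changes of the 2 comparisons had r = -0.05 across genes against -0.49 in the simulations, and a covariance of -0.00861 against -0.0206. The opposed count was 0 without blank control replicate 1, 19 without blank control replicate 2, 7 without negative control replicate 3, and 1 without negative control replicate 2 or without Firre overexpression replicate 3. The count that moved the same way was 0 without blank control replicate 1 or negative control replicate 1, 24 without blank control replicate 2, and 3 without blank control replicate 3, negative control replicate 2 or Firre overexpression replicate 3.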

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

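The tests of explanations in this part were all chosen after the result they bear on was seen, while the counts over other groupings of the libraries were planned beforehand. Outside the gene counts, ambiguous reads made up 3.31%, 3.45% and 3.20% of all counts in the Firre libraries, each above the highest negative control at 3.12%, although the highest blank control had 3.21%. Reads that did not align uniquely made up 8.18%, 7.79% and 8.21% with Firre, each above the highest negative control at 7.34%, and the highest blank control had 7.98%.

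Macrophage, epicardial, fibroblast and endothelial markers were lower, and sarcomere genes higher, in the Firre libraries, while Schwann cell and neuron markers and adipocyte markers were not called. The tables argue against a single smaller share of all non-myocyte cells as the only change. The macrophage median minus the fibroblast median was -2.74 (95% bootstrap interval -4.08 to -0.55, and -3.04 to -2.12 over the Firre libraries). They argue likewise against a larger share of the same cardiomyocytes alone, since the atrial median minus the ventricular median was 0.88 (0.61 to 1.20). Both arguments hold only if marker levels within each cell type stayed the same. Within the endothelial list Vwf fell by 3.38 and Cdh5 by 1.42, so a shared loss of non-myocytes together with other changes stays open. A trend with GC content or transcript length is argued against too: the sarcomere median minus the fibroblast median was 1.90 before its removal and 1.89 after (1.51 to 2.21), and the trend took up 0.699% of the variance over 15613 genes. The lists are not pure: other fixed lists also hold 5 of the 18 fibroblast, 9 of the 13 atrial and 8 of the 10 ventricular markers and none of the 17 macrophage markers, while 17, 13, 10 and 15 of these reach 1 CPM in the negative control, led by Col1a1 (4227 CPM), Nppa (3409), Pln (1484) and Lyz2 (29.8). A loss of macrophages beyond that of the other non-myocytes also stays open, as does another mix of atrial and ventricular cells in these preparations. So do a batch and an effect of Firre. The labels name no such loss, mix or batch, and a candidate explanation that combines them could not be tested.

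All 44 interferon-stimulated genes rose with Firre. The tables argue against more macrophages in the Firre libraries, since the macrophage median was -3.87 (95% bootstrap interval -5.10 to -1.57, and -4.17 to -3.18 over the Firre libraries). Lyz2 was at 0.738 CPM against 29.8 CPM in the negative control. For neutrophils and lymphocytes 1 and 3 markers were tested, at medians of -2.15 and -3.31, too few to decide on other immune cells. If the blank control received no vector, which its label does not say, the tables also argue against AAV9 particles as given to the negative control. The median of the interferon-stimulated genes between the controls was -0.075 (-0.13 to 0.00). The dose, purity and insert of the Firre vector may differ from those of the control vector and are confounded with the group, as is any culture batch, so these and an effect of the Firre RNA itself cannot be told apart. As a hypothesis, sensing of vector-derived nucleic acid could be followed up with a control RNA of the same length at the same dose.

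Cell cycle genes fell with Firre while histone genes rose. Fewer non-myocyte cells could account for the fall: the mitosis median minus the fibroblast median was 0.23 (95% bootstrap interval -0.15 to 0.50, and 0.19 to 0.28 over the Firre libraries), an interval that holds a fall equal to that of the fibroblast markers. That leaves a fall of these genes within cardiomyocytes open, since bulk counts do not part the cell types. For the histone genes, more RNA without a polyA tail was tested on small RNAs, whose median minus the histone median was -1.41 (-2.30 to -0.84); only 5 such genes were tested, at a median of 0.556 CPM, too few and too low to decide. Reads shared between histone copies stay open as well, as does the low-count filter, since only 11 of 20 histone genes reached 1 CPM in the negative control.

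With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split of the Firre and negative control libraries gave 8747 genes and 29 lists. The highest of the other splits gave 0 genes and 23 lists, so the real one was 1 of 10 for each. Against the blank control the real split gave 8796 genes and 27 lists, the highest other 0 genes and 24 lists. Each other split mixed Firre and control libraries in both groups, which put the Firre difference into the spread within groups. These counts of 0 genes therefore decide nothing. Camera still called 20 to 23 lists in the mixed splits with the negative control. Between the controls the real split gave 9 genes, with 2 in the highest other, and 14 lists, a number that 2 of the 10 splits reached. For the 9 libraries together, 100 assignments to groups were drawn: 7697 genes called against both controls, and 2 opposed genes, were reached by the real assignment alone (1 of 100, highest other 0 for each). Of the 99 others, however, only 1 kept the 3 Firre libraries in a group of their own and the rest put the Firre difference into the spread within groups, so these counts of 0 decide nothing.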

How the results depend on the processing

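All alternatives in this part were planned. For Firre overexpression against the negative control the count of 8747 genes lay between 8165 and 8923 with other scalings, filters, tools, groups in the fit and gene types, and between 7938 and 8128 without 1 library, where fewer samples enter. DESeq2 called 8165, of which 8142 were among the 8747, and limma-voom 8764, of which 8643 were. Against the blank control the count of 8796 became 7947 to 8295 without 1 library, and for both controls the 7697 became 6945 to 7449. Firre's log2 fold change was 0.92 to 0.998 without 1 library. A log2 threshold of 1 left 1878 genes against the negative control, 1954 against the blank control and 1591 against both, by its construction, and Firre at 0.97 fell just short of it.

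The small counts moved most, and where a setting's construction does not show it the cause was not tested. Between the controls the 9 genes became 98 with no low-count filter (31 higher, 67 lower), 32 with DESeq2 (17 higher, 15 lower; 3 of the 9 among them, while its independent filtering gave no adjusted p to 14548 genes, 6 of the 9 included), 5 with limma-voom, 2 with no robust prior and 0 with a log2 threshold of 1. They numbered 0 to 55 without 1 library: 0 without blank control replicate 1, 55 without blank control replicate 2, 3 without negative control replicate 1, 4 without negative control replicate 2 and 15 without negative control replicate 3. Beside that 0 of edgeR, 1037 genes had an unadjusted p under 0.05, DESeq2 called 6 and limma-voom 0. Beside the 0 of the log2 threshold, 85 genes past it had an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0, with 55 and 88 such genes. The 2 opposed genes became 1 with DESeq2 size factors, library totals, the stricter filter, limma-voom, the replicate block or no robust prior, 35 with no filter, 16 with DESeq2 and 0 with a log2 threshold of 1. Without 1 library they numbered 0 (blank control replicate 1) to 19 (blank control replicate 2). The 7 that moved the same way became 40 with no filter, 9 with DESeq2, 4 with limma-voom, 1 with no robust prior and 0 with a log2 threshold of 1, and 0 to 24 without 1 library.

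Lists called by camera numbered 17 with an estimated correlation against 29 for Firre overexpression vs negative control, 16 against 27 for the blank control and 0 against 14 between the controls, where fry called 1. Without 1 library they numbered 29 to 31, 27 to 28 and 9 to 15, the 9 without blank control replicate 1. The reversals were in genes that did not pass in any setting. Between the controls Akt2 was at -0.0039 with upper-quartile scaling (adjusted p = 0.991), -0.0060 without negative control replicate 1 (0.990) and -0.00087 without negative control replicate 2 (0.9996), where leaving out 1 library gave -0.0060 to 0.0238 and all alternatives had an adjusted p of 0.952 to 1. Akt1 was at 0.0285 without blank control replicate 3 (0.935) and 0.0153 without negative control replicate 2 (0.982), with -0.0350 to 0.0285 without 1 library (all alternatives 0.935 to 1), and Firre at 0.0508 without blank control replicate 2 (0.862), with -0.10 to 0.0508 without 1 library (all alternatives 0.783 to 0.990). The cause was not tested. Of the values of named genes under alternatives, Firre against the negative control left aside, 872 against the negative control, 570 between the controls and 619 against the blank control kept their direction and side of the threshold, 9, 50 and 9 fell short of it and 1, 25 and 1 newly passed. Against either control the 9 that fell short did so with the log2 threshold of 1, by its construction, as did Firre against the negative control, and the 1 that newly passed was Akt1 with library totals.

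Replicate numbers do not pair the samples: correlations of deviations from the group means ran from -0.04 to 0.03 for libraries of the same number and from -0.05 to 0.06 for others. With the replicate block edgeR called 8592 genes against the negative control, 7 between the controls (4 of the 9 among them) and 8586 against the blank control. The block brought in the ribosomal list against the negative control (0.0492; all alternatives 7.57e-03 to 0.795) and apoptosis regulators against the blank control (0.0474; all alternatives 8.68e-05 to 0.101). Depth was 15591542 to 22697016 counts per library, which limits what can be said of genes near the filter.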

Other observations

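The gene groups in this paragraph were chosen after the data were seen, as 4 further lists. Genes of MHC class I antigen presentation, which interferon is known to induce, rose in 19 of 24 and fell in 3 with Firre against the negative control (median log2 fold change 1.04, camera adjusted p = 1.98e-08, and adjusted p = 6.83e-03 with an estimated correlation). H2-D1 rose by 1.32 (SE 0.05), from 107 ± 2.83 to 266 ± 4.20 CPM (SD, n = 3), H2-T24 by 3.93, Tap2, a subunit of the peptide transporter, by 1.54 and the light chain gene B2m by 0.89; H2 genes share reads between copies and are uncertain. Genes of the TCA cycle and pyruvate dehydrogenase rose in 27 of 29 and none fell (median 0.67, adjusted p = 1.01e-17, and adjusted p = 6.83e-03 with an estimated correlation), with Pdk4, a kinase that turns pyruvate dehydrogenase off, at 1.94, and Pdhb going from 175 ± 2.74 to 350.4 ± 10.7 CPM. Fibroblast markers fell in the same libraries (median -1.12).

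Complement components and regulators, from the same set of lists, fell in 12 of 17 and rose in 1 (median -0.61, adjusted p = 4.95e-05, and adjusted p = 6.83e-03 with an estimated correlation). C1s1, a protease of the classical pathway, fell by 3.15 (SE 0.11), the regulator gene Cd55 by 1.65, and C3 by 1.54; macrophage markers fell with them (median -3.87). Between the controls the complement list was called lower too (median -0.10, adjusted p = 4.14e-03, and adjusted p = 0.0493 with an estimated correlation), and MHC class I genes were called lower (median -0.06, adjusted p = 7.49e-03) but not with an estimated correlation (adjusted p = 0.139). No member of either list passed over all genes tested, and 2 of 17 and 1 of 24 were lower adjusted over the list alone. Macrophage markers were lower between the controls as well (median -0.45). With Firre against the negative control, interferon receptors and signalling genes went both ways, with 4 of 14 higher and 8 lower (adjusted p = 0.284). The receptor chain gene Ifnar1 fell by 0.42 and the kinase gene Jak1 by 0.21, while the double-stranded RNA sensor gene Tlr3 rose by 1.11. Of the sensor genes, Tmem173, which encodes STING, fell by 1.08. Tlr7 fell by 3.18 at low levels, from 1.68 ± 0.281 to 0.187 ± 0.135 CPM (SD, n = 3). Macrophage markers fell in the same libraries, and the bulk counts do not say in which cells these genes were expressed. For this comparison all 4 medians kept their sign under each of the scalings tried.

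Interferon ligand genes had few counts. Over 21 such genes the 3 libraries of the blank control had 4 counts together, those of the negative control 3 and those of the Firre group 14. Ifnb1, the gene of interferon beta, had 5, 1 and 3 counts in the Firre libraries and 0 in all 6 controls. Against a floor of 3 counts over the group, its level was at least 2.96-fold that of the negative control. Against the blank control the bound was at least 2.64-fold. These bounds take the few Firre counts as exact, so the true fold could be lower. Ifng had 0 counts in every library, so it was not detected at this depth.

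Of the genes called against the negative control, 814 rose by more than Firre on the log2 scale and 1163 fell by more; the median absolute log2 fold change of the called genes was 0.53, against 0.97 for Firre. Ptbp3, a paralog of Ptbp1, fell by 0.79 (adjusted p = 1.21e-10) and Ptbp2, the neuronal paralog, had a value of -0.19 that did not pass (adjusted p = 0.170); both are named after their values were seen. The nuclear RNAs Malat1 and Neat1 had values of 0.03 and -0.10 and did not pass. Xist, transcribed from the inactive X of female cells, was at 285 to 386 CPM and the Y-linked gene Ddx3y at 32.9 to 42.0 CPM in the 9 libraries, so transcripts of both kinds were present in each library.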
